A study of Mus musculus with 6 samples.

How the data were processed

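RNA from whole embryonic lung buds was measured on 6 arrays, 3 of control lungs (Shh cre/+) and 3 of lungs that carried the same Cre and a floxed Fzd2 gene. Lungs were dissected at stage E12.5 and 100 ng of total RNA per array was amplified from a poly(T) primer and labelled with biotin, per the labels' protocols. The authors deposited log2 expression values, 1 table for all arrays, made with oligo and RMA per the submitters' processing notes. RMA corrects background, normalizes the distributions of the arrays to each other and summarises probes into probe sets; versions, the probe set level and any filter are not given in the sources used here. That the scale is log2 was read from the values, which run from 3.55 to 14.04 with medians from 7.29 to 7.32. Because each array was forced to a common distribution, only changes relative to the bulk of genes can be seen, and differences near the top and bottom of the scale are compressed.

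Of 41345 probe sets, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 16010 were unnamed here. Entrez identifiers of 23328 probe sets were found in the reference gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used only for names and for which genes neighbour each other, since no build is named for the arrays. Probe sets with 1 symbol gave 22180 genes; for the 1082 genes with several, the probe set with the highest mean over all arrays was used. No filter on dim probe sets was applied. The 17824 probe sets with several symbols or none were tested separately with the same model, which called 0, with 2175 at an unadjusted p under 0.05.

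Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, group as the only term, two-sided, Benjamini-Hochberg adjusted p over all genes, threshold 0.05). A log2 difference is mutant minus control throughout, with limma's standard error. Gene lists were tested with camera from the same package at a preset inter-gene correlation of 0.01, adjusted over 31 lists; a list needed at least 4 measured genes. No list call held with an estimated correlation, where 3 lists (p53 response, pan-epithelial, tight and adherens junctions) were at an unadjusted p under 0.05, and none held with fry, which tests whether a list's genes move 1 way on balance (adjusted p = 0.0531 for those 3 lists, and 5 lists at an unadjusted p under 0.05). Members of a list were also adjusted over the list alone. Some genes stand in more than 1 list. The result of 1 of the lists is not reported here.

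The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, apart from those said to be chosen later. The rule names the Frizzled genes; in each direction the 12 genes with the smallest p among those above the 30th percentile of mean expression, with an absolute log2 difference of at least 0.26 and all 3 mutant arrays on 1 side of all 3 controls; and for each list up to 4 members that passed over the list alone or, where none passed, the 2 to 4 with the smallest p. Symbols of predicted transcripts were counted but not named. Lists of adult small intestine and adipose tissue genes were written after the data had been seen.

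Simulated data with the arrays' own spread were used to test the procedure: of genes changed by 0.5 and by 1 on the log2 scale, 67% and 94% were recovered, 7 of 168 calls were false, and camera called both shifted lists and 0 others. The simulated genes varied independently, which those of a real list need not do: on the deposited values camera called at least 4 and up to 16 lists in each other split of the 6 arrays into 3 and 3. Alternatives were another normalization, filters on dim genes, other summaries of probe sets, other variance models, array weights, the replicate number as a block, the Y-linked or pan-epithelial mean as a covariate, each array left out, other thresholds and other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.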

Results

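Gene expression was measured on 6 microarrays of whole lung buds from mouse embryos at stage E12.5, when the airway tree is branching. The control group was 3 lungs with 1 copy of a Cre recombinase allele at the Shh gene, and the mutant group was 3 lungs that carried the same Cre allele together with a floxed Fzd2 gene on both chromosomes. Shh is expressed in the epithelium of the lung, so the design aims at deletion of Fzd2, which encodes a Frizzled receptor for Wnt ligands, in the epithelium and not in the surrounding mesenchyme. No array measured either compartment alone. The stated purpose was to find genes that depend on Fzd2 signalling in the lung epithelium. Each array was made from 100 ng of total RNA and gave log2 expression values for 41345 probe sets, from which 22180 genes were tested. Array medians over all probe sets lay between 7.29 and 7.32, and the number of arrays, 3 per group, limits the precision of every value. The labels call the arrays biological replicates; whether a replicate was 1 lung or a pool is not given in the sources used here.

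Fzd2 itself was lower by a log2 difference of -0.29 (SE 0.15, n = 3 and 3) in mutant lungs, 82.1% of the control level, which limma did not separate from the spread between arrays (adjusted p = 0.475). The log2 values were 9.57, 9.82 and 9.75 in control replicates 1 to 3 and 9.67, 9.07 and 9.54 in mutant replicates 1 to 3, so the array labelled mutant replicate 1 lay within the control range. A two-sided exact permutation test gave p = 0.2, where 3 arrays against 3 cannot give less than 0.1. Without mutant replicate 2 the log2 difference was -0.10, and with the pan-epithelial mean as a covariate it turned to 0.38 (adjusted p = 0.873). The whole lung was measured, and where the probe set lies relative to the deleted part of Fzd2 is not given in the sources used here, so this value is a weak check of the labels. No other Frizzled gene passed limma's threshold. The smallest p among them was that of Fzd3, with a log2 difference of -0.12 (SE 0.05, adjusted p = 0.396), and Fzd1, Fzd4, Fzd5, Fzd6, Fzd7, Fzd8, Fzd9 and Fzd10 had log2 differences between -0.11 (Fzd10) and 0.14 (Fzd9). The value of Fzd10 ran from -0.18 without mutant replicate 3 to -0.02 without mutant replicate 2, and that of Fzd9 from 0.02 without control replicate 2 to 0.27 without control replicate 1.

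Among single genes, limma called 14 at an adjusted p under 0.05, 4 higher and 10 lower in mutant lungs, with changes of 1.40- to 1.74-fold. Among the lower genes were Myo5c, an unconventional myosin of secretory epithelia (log2 difference -0.77, SE 0.06, adjusted p = 0.0221), Exph5, an effector of the vesicle GTPase Rab27 (-0.67, SE 0.05, adjusted p = 0.0221), and the aspartic protease gene Cym (-0.80, SE 0.07, adjusted p = 0.0238). Others were the guidance factor gene Sema3e (-0.64, SE 0.06, adjusted p = 0.0238) and Esrp1, an epithelial regulator of RNA splicing (-0.48, SE 0.05, adjusted p = 0.0334). Cep112, which encodes a centrosomal protein, and Cep112it, named as a transcript from within its introns, fell by 0.54 and 0.53 on the log2 scale, and the surfactant-associated pseudogene Sfta3-ps fell by 0.59. The other 2 lower genes, Gm20554 and 9030622O22Rik, carry symbols of predicted transcripts and were named after their values were seen. They fell by 0.67 and 0.55. The 4 higher genes were Eda2r, a receptor of the tumour necrosis factor receptor family (0.66, SE 0.07, adjusted p = 0.0334), Megf10, an engulfment receptor (0.62, SE 0.06, adjusted p = 0.0289), Ccng1, a target of the tumour suppressor p53 (0.54, SE 0.06, adjusted p = 0.0368), and the matrix proteoglycan gene Dcn (0.54, SE 0.05, adjusted p = 0.0238). In all 12 named genes the 3 mutant arrays lay on 1 side of the 3 control arrays, which the naming rule required.

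**Figure D1:**
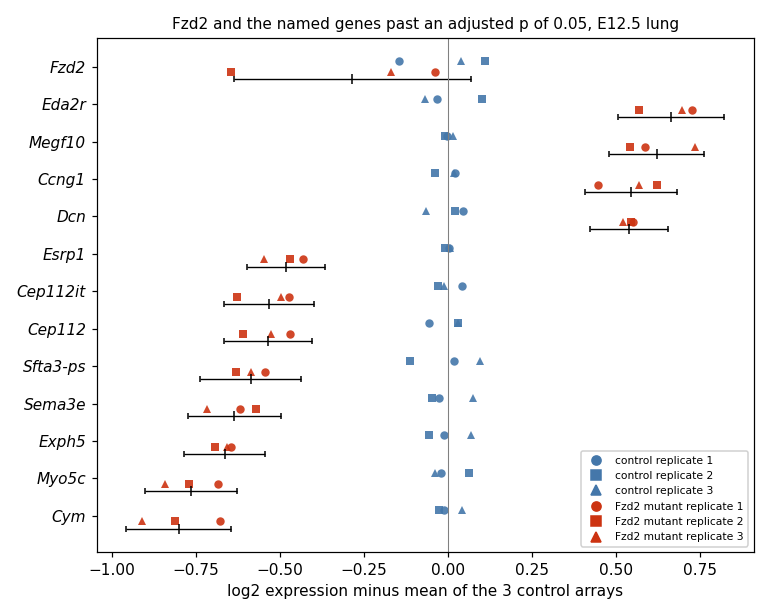
Log2 expression of Fzd2 and the 12 named genes past limma's adjusted p of 0.05, each array plotted as its difference from the mean of the 3 control arrays (blue, control; red, Fzd2 mutant; circle, square and triangle, replicates 1, 2 and 3). Black ticks and bars give the mean difference and its 95% confidence interval from limma; the mutant arrays of Fzd2 overlap the controls, while those of the 12 called genes lie apart from them, from -0.80 on average for Cym to 0.66 for Eda2r.

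At an adjusted p under 0.10, limma counted 57 genes, 16 higher and 41 lower. Lower genes between the thresholds included Mpzl2, an epithelial adhesion molecule (log2 difference -0.55, SE 0.06, adjusted p = 0.0509), Cckar, the cholecystokinin A receptor (-0.84, SE 0.10, adjusted p = 0.0509), the Iroquois transcription factor gene Irx2 (-0.42, adjusted p = 0.0521) and the matrix protein gene Smoc2 (-0.62, adjusted p = 0.0556). Higher genes between the thresholds included Ccdc43 (0.59, SE 0.07, adjusted p = 0.0509), the Na,K-ATPase regulator Fxyd1 (0.38), the forkhead gene Foxc2 (0.33), Eml5 (0.31), the adhesion molecule gene Lrfn5 (0.87, SE 0.12, adjusted p = 0.0778), the p53 target Trp53inp1 (0.46), Galnt14 (0.35) and the elastic fibre gene Fbln5 (0.54). At an unadjusted p under 0.01 more genes were higher (436) than lower (342). At an unadjusted p under 0.05 there were 2770 genes, and in 4301 genes (19.4%, where chance gives 10%) the groups did not overlap. The count of 14 depended on the arrays: leaving out any of the 6 arrays gave 0 genes by limma, with 1797 to 3084 genes at an unadjusted p under 0.05. The 12 named genes kept their direction in each of those 6 fits. Genes whose groups do not overlap must do so, and the naming rule required that, so it adds no support.

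Of 28 measured pan-epithelial genes, which are shared by epithelia, 27 had lower mean values in mutants, with a median log2 difference of -0.26, and 17 fell at an adjusted p under 0.05 adjusted over the list alone, against 1 (Esrp1) over all genes tested. Examples were Esrp1, its paralog Esrp2 (-0.42, SE 0.05), the lung and thyroid transcription factor Nkx2-1 (-0.41, SE 0.05) and the apical membrane protein gene Prom1 (-0.33, SE 0.05). The gene with a higher mean was Perp (0.52, SE 0.20), named after its values were seen, which is also a p53 target. Camera, which compares a list with all other genes, placed the list lower (adjusted p = 3.34e-19), and with adjusted p = 0.258 with an estimated correlation the call was lost. The mean of the list differed from the control mean by -0.18, -0.33 and -0.20 log2 units in mutant replicates 1, 2 and 3. The lowest of these, mutant replicate 2, also stood apart in genes known from adipose tissue, such as Fabp4 at 12.92 against at most 8.52 elsewhere. Control replicate 1, which stood apart in genes known from adult small intestine, had the highest list mean, 9.01 against 8.99 and 8.93 in the other controls. Without control replicate 1 and mutant replicate 2 together the median was -0.18 (camera adjusted p = 3.44e-11). Of 23 tight and adherens junction genes, 21 had lower means, with a median of -0.11. Of these, 6 fell adjusted over the list alone and 0 over all genes, among them the E-cadherin gene Cdh1 (-0.37, SE 0.06), the claudin gene Cldn4 (-0.29), the occludin gene Ocln (-0.28) and the polarity gene Llgl2 (-0.23). Cdh1, Cldn3, Cldn4, Cldn6 and Cldn7 also stand in the pan-epithelial list, so the junction result partly restates the pan-epithelial one. Camera gave the junction list adjusted p = 5.14e-08, and adjusted p = 0.346 with an estimated correlation. Only 3 members passed without mutant replicate 2, without control replicate 2, or without mutant replicate 2 and control replicate 1 together, where the median was -0.08.

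Genes known from the branching tips of the epithelium, some of which, such as Bmp4 and Id2, are also expressed outside it, moved in both directions. Of 16 distal tip genes, 5 fell and 4 rose adjusted over the list alone, and 0 changed over all genes. The stem cell receptor gene Lgr5 (-0.48, SE 0.06) and the proto-oncogene Mycn (-0.30, SE 0.06) fell, while Spry2, a feedback inhibitor of FGF signalling (0.30, SE 0.04), and the clusterin gene Clu (0.32, SE 0.07) rose. Camera did not call the list (adjusted p = 0.110). Sox2, the transcription factor of the proximal airway, fell by 0.66 (SE 0.14) adjusted over its list alone, as the only 1 of 12 proximal airway genes to pass, and 0 passed over all genes. The proximal list was not called (adjusted p = 0.494), and its median (0.03) differed in sign from its mean (-0.04) and its test. Of 28 basement membrane and integrin genes, the laminin gene Lamb3 (-0.26, SE 0.05) fell adjusted over the list alone and 0 changed over all genes. The list was not called (adjusted p = 0.0660).

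Of 22 feedback and target genes of canonical Wnt signalling, 14 had lower and 8 had higher means in mutant lungs, with a median log2 difference of -0.05. Adjusted over the list alone, 3 fell and 1 rose, and 0 changed over all genes. Those that fell were the R-spondin receptor gene Lgr5 (-0.48) and the ubiquitin ligase genes Rnf43 (-0.32, SE 0.05) and Znrf3 (-0.30, SE 0.06), which remove Frizzled receptors from the cell surface. The one that rose was Wif1, which encodes a secreted Wnt inhibitor (0.31, SE 0.07). Axin2, a commonly used Wnt target named after its values were seen, had a log2 difference of -0.05 (SE 0.08). Camera called the list lower (adjusted p = 0.0367), with adjusted p = 0.661 with an estimated correlation. The call was also lost without mutant replicate 2 (adjusted p = 0.254), mutant replicate 3 (0.137), control replicate 2 (0.0982) or control replicate 3 (0.0724), and without control replicate 1 and mutant replicate 2 together (0.128). The median was -0.10 without mutant replicate 1, -0.08 without control replicate 1 and -0.03 without control replicate 3, -0.01 after a further quantile normalization and -0.10 over genes above the 50th percentile of expression. Other settings that ended the call included the 30th percentile filter (adjusted p = 0.113), averaged probe sets (0.0979) and a rank-based camera (0.149). The Y-linked mean as a covariate also ended it (0.0924), which nearly repeats the fit without control replicate 2, the only array without Y-linked signal. Of this list, 2 genes in place of 4 passed without mutant replicate 3 or control replicate 2, and the median turned to 0.0535 with the pan-epithelial mean as a covariate. The list of Wnt ligands also holds Porcn and Wls, which act in Wnt secretion. None of its 21 measured genes passed adjusted over the list alone or over all genes by limma (1 at an unadjusted p under 0.05), and the list was not called (adjusted p = 0.227). Those with the smallest unadjusted p were Wnt6 (0.19, SE 0.08) and Wnt9a (0.17, SE 0.08). The list of Wnt receptors and coreceptors leaves out Fzd2 and also holds the secreted antagonist genes Sfrp1, Sfrp2, Sfrp5 and Frzb. Of its 18 genes, Sfrp2 (0.31, SE 0.07), which is not a receptor, rose adjusted over the list alone and 0 changed over all genes (list adjusted p = 0.776).

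Planar cell polarity genes, through which Frizzled receptors act without beta-catenin, were not called as a group. Celsr1, a core polarity cadherin, fell by 0.45 (SE 0.08) adjusted over the list alone, the only 1 of 23 polarity genes to do so, with 0 over all genes. The list had a median of -0.07 and camera gave adjusted p = 0.0662.

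Of 21 lung mesenchyme genes, 14 had higher and 7 had lower means in the mutants, and 3 rose adjusted over the list alone and 1 (Dcn) over all genes: Dcn (0.54), the related proteoglycan gene Lum (0.61, SE 0.11) and the homeobox gene Prrx1 (0.50, SE 0.10). Camera called the list higher (median 0.10, adjusted p = 0.00715), with adjusted p = 0.505 with an estimated correlation, and the adjusted p was 0.0563 without mutant replicate 1 and 0.0518 without control replicate 1, and 0.0516 by a rank-based camera. The 7 genes with lower means, named after their values were seen, had small differences. They were Tcf21 (-0.10), Tbx5 (-0.09), Meox2 (-0.08), Foxf1 (-0.06), Tbx4 (-0.05), Hoxa5 (-0.02) and Wnt2 (-0.0036). Without mutant replicate 3, 6 mesenchyme genes rose adjusted over the list alone. Of 15 smooth muscle genes, 12 had lower means, and 2 fell adjusted over the list alone with 0 over all genes, namely the smooth muscle actin gene Actg2 (-0.38, SE 0.08) and Myocd, the master coactivator of smooth muscle genes (-0.42, SE 0.10). Camera called that list lower (median -0.11, adjusted p = 0.000316), with adjusted p = 0.505 with an estimated correlation. None of its genes passed (0 by limma) without mutant replicate 1 or without mutant replicate 3, and 1 without control replicate 2.

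Of 17 leukocyte genes, 13 had higher means, and 3 rose adjusted over the list alone and 0 over all genes, the macrophage receptor gene Cx3cr1 (0.30, SE 0.05) and the immune receptor adaptor genes Tyrobp (0.33, SE 0.06) and Fcer1g (0.30, SE 0.06). Camera called the list higher (median 0.16, mean 0.05 with SE 0.11, adjusted p = 0.000838), with adjusted p = 0.592 with an estimated correlation. The list also holds Lyz1, at 10.96 in control replicate 1 and at most 6.05 elsewhere, so that its mean was lower in mutants. The other genes with lower means, named after their values were seen, were Ptprc (-0.03, SE 0.07), Cd68 (-0.02, SE 0.06) and Mrc1 (-0.01, SE 0.07). Without control replicate 1 and mutant replicate 2 together, 7 leukocyte genes rose adjusted over the list alone, and 5 without mutant replicate 2. The median of the list was 0.10 without mutant replicate 3. Gpm6a (0.37, SE 0.06) was the only 1 of 11 mesothelial genes to rise adjusted over the list alone, with 0 over all genes, and camera called that list (median 0.13, adjusted p = 0.0246), with adjusted p = 0.661 with an estimated correlation. That call was lost without mutant replicate 1 (median 0.06, adjusted p = 0.224) or control replicate 3 (median 0.09, adjusted p = 0.118), and 2 genes passed without mutant replicate 2. In the neural crest and neuron list, Stmn2 (0.38) and Hand2 (0.37) rose and the neuregulin receptor gene Erbb3 (-0.36) fell adjusted over the list alone, 0 of 12 over all genes, and camera gave adjusted p = 0.0662. None of 20 endothelial and 10 erythroid genes passed adjusted over their lists alone or over all genes by limma (1 in each at an unadjusted p under 0.05), and camera gave adjusted p = 0.308 and 0.366. Lowest by p were Erg (-0.18, SE 0.07) and Flt1 (0.10, SE 0.06) among endothelial and Tfrc (-0.14, SE 0.05) and Gata1 (0.14, SE 0.07) among erythroid genes.

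Of 15 measured genes of the p53 response and apoptosis, 13 had higher means in mutant lungs, and 3 rose adjusted over the list alone and 1 (Ccng1) over all genes: the cell cycle inhibitor gene Cdkn1a (0.97, SE 0.19), Ccng1 (0.54, SE 0.06) and Trp53inp1 (0.46, SE 0.07). Camera called the list higher (median 0.14, adjusted p = 0.000313), with adjusted p = 0.258 with an estimated correlation. The median was 0.08 without mutant replicate 2, 0.09 without that array and control replicate 1 together, and 0.23 without mutant replicate 3. The list mean lay above the controls in each mutant array, and in mutant replicate 2 its member Mdm2, named after its values were seen, stood at 11.83 against at most 10.01 elsewhere. Of 27 mitosis and S phase genes, 25 had lower means, with a median of -0.07, and 0 passed by limma adjusted over the list alone or over all genes (4 at an unadjusted p under 0.05). Members with the lowest p were the replication genes Cdc6 (-0.16, SE 0.06), Rrm2 (-0.19, SE 0.08), Mcm2 (-0.19, SE 0.08) and Ccne1 (-0.13, SE 0.05). Camera called that list lower (adjusted p = 0.000254), with adjusted p = 0.661 with an estimated correlation, and without mutant replicate 2 the median was -0.03 and the adjusted p was 0.0525. After a further quantile normalization the median was -0.04. The list mean of mutant replicate 1 lay within the control range. The mitosis median turned to 0.11 with the pan-epithelial mean as a covariate, as did that of the hypoxia list to -0.29. Hypoxia and glycolysis genes were called higher (median 0.21, adjusted p = 0.0116), with adjusted p = 0.661 with an estimated correlation. Of 14 genes, 2 rose adjusted over the list alone, Ndrg1 (0.28, SE 0.05) and the glucose transporter gene Slc2a1 (0.22, SE 0.06), and 0 over all genes. That shift lay mostly in mutant replicate 2, and without it the median was 0.05 and camera gave adjusted p = 0.447. With averaged probe sets the median was 0.14. Without it and control replicate 1 together the median was 0.07 (adjusted p = 0.695). At most 1 hypoxia gene passed over the list alone without any single array other than mutant replicate 3.

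**Figure D2:**
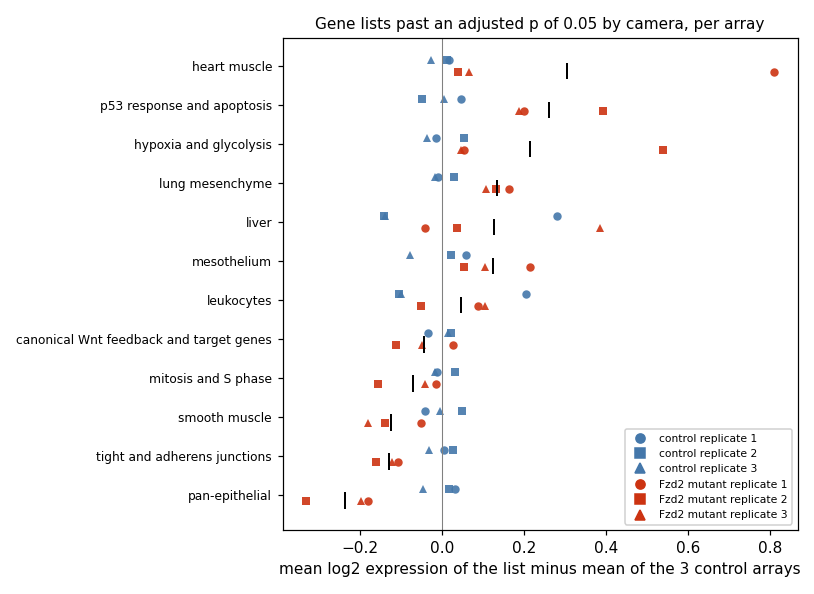
Mean log2 expression per array of the 12 gene lists called by camera, plotted as the difference from the mean of the 3 control arrays (blue, control; red, Fzd2 mutant; symbols, replicates 1 to 3; black ticks, mean of the 3 mutant arrays). The 3 mutant arrays lie below all controls for the pan-epithelial, junction and smooth muscle lists and above them for the mesenchyme, p53 and heart muscle lists; the heart muscle shift comes mostly from mutant replicate 1 and the hypoxia shift from mutant replicate 2.

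With the pan-epithelial mean as a covariate, which is nearly tied to the group, the pan-epithelial, junction, canonical Wnt, mesenchyme, smooth muscle, p53 and liver lists were no longer called. The medians were 0.10 for the mesenchyme (adjusted p = 0.0529), -0.09 for the smooth muscle (adjusted p = 0.243) and 0.12 for the p53 list (adjusted p = 0.734), against 0.10, -0.11 and 0.14 without the covariate. Those of the pan-epithelial list, whose own mean is the covariate, and of the junction, canonical Wnt and liver lists moved to 0.01, -0.03, 0.05 and 0.38. The medians of the mesothelium, leukocyte and heart muscle lists were 0.31, 0.33 and 0.84 with that covariate.

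Other signalling lists were not called by camera. In the FGF response list, the early response gene Egr1 (0.25, SE 0.06) and Spry2 (0.30) rose and the receptor gene Fgfr2 fell by 0.22 (SE 0.06) adjusted over the list alone, 0 of 17 over all genes (list adjusted p = 0.675). In the retinoic acid list, the retinaldehyde dehydrogenase gene Aldh1a1 fell by 0.46 (SE 0.08) and the retinaldehyde reductase gene Dhrs3 (0.21, SE 0.06) rose adjusted over the list alone, 0 of 13 over all genes (list adjusted p = 0.460). In the stress and immediate early list, Jun fell by 0.25 (SE 0.06) and Egr1 rose adjusted over the list alone, 0 of 18 over all genes (list adjusted p = 0.558). By limma, 0 of 14 Hedgehog, 21 BMP and TGF-beta and 20 Notch genes passed adjusted over their lists alone or over all genes (4, 4 and 3 at an unadjusted p under 0.05), and camera gave adjusted p = 0.308, 0.298 and 0.392. Lowest by p in these lists were Hhip (-0.23, SE 0.06) and Ptch1 (-0.18, SE 0.05), Id3 (0.30, SE 0.08) and Tgfbi (-0.15, SE 0.06), and Nrarp (0.13, SE 0.05) and Hey2 (0.17, SE 0.06).

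Genes of tissues next to the lung were uneven between single arrays. Heart muscle genes were called higher by camera (median 0.18, adjusted p = 0.00847), with adjusted p = 0.661 with an estimated correlation, but 0 of 15 passed by limma adjusted over the list alone or over all genes (2 at an unadjusted p under 0.05). Its members with the lowest p were Nkx2-5 (0.18, SE 0.06), Tnni1 (0.31, SE 0.12), Tnnc1 (0.51, SE 0.26) and Tnnt2 (0.61, SE 0.37). In mutant replicate 1 the cardiac myosin genes Myh6 and Myl7 stood at 9.25 and 11.20, against at most 7.09 and 9.18 in the other arrays, and without that array the median was 0.06 and the list call was lost (adjusted p = 0.213). The heart muscle median was 0.37 over genes above the 50th percentile of expression and 0.08 without genes seen in 1 array alone. Liver genes were called higher (median 0.14, adjusted p = 0.0412), with adjusted p = 0.661 with an estimated correlation, and 0 of 13 passed by limma adjusted over the list alone or over all genes (1 at an unadjusted p under 0.05). Ranked by p, the list was led by Afp (1.14, SE 0.37), Alb (0.26, SE 0.12), Fgb (0.14, SE 0.07) and Fga (0.20, SE 0.11). Afp stood at 7.94, 8.10 and 9.53 in mutant replicates 1, 2 and 3, against at most 7.50 in the controls. The list mean was highest in mutant replicate 3 (7.03) and next in control replicate 1 (6.93). The list call by camera was lost without mutant replicate 3 (median 0.08, adjusted p = 0.254), without control replicate 2 (0.140) or without control replicate 3 (0.126). Over the list alone, 2 genes passed without mutant replicate 1 and 1 without mutant replicate 3. The liver median was 0.21 without control replicate 1 and mutant replicate 2 together. The call by camera was also lost after a further quantile normalization (adjusted p = 0.145) and with the 30th percentile filter (0.159). It was lost too with the Y-linked mean as a covariate (0.125), which nearly repeats the fit without control replicate 2. By limma, 0 of 12 skeletal muscle and 14 cartilage genes passed adjusted over their lists alone or over all genes (0 and 5 at an unadjusted p under 0.05), and camera gave adjusted p = 0.140 and 0.675. Ranked by p, these lists were led by Myod1 (0.14, SE 0.06) and Acta1 (0.14, SE 0.06) and by Hapln1 (-0.30, SE 0.08) and Col2a1 (-0.23, SE 0.07). The cartilage median (0.04) and mean differed in sign from camera's direction.

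Control replicate 2 differed from the other 5 arrays in sex-linked genes. Xist, transcribed from the inactive X chromosome, stood at 12.07 there against 6.28 and 5.75 in the other control arrays. The Y-linked genes Uty and Eif2s3y lay far below their level in the other arrays, with Eif2s3y at 5.73 against at least 10.51 elsewhere. Their group differences were 1.70 (SE 1.25) and 1.59 (SE 1.20). With Xist high and Y-linked genes low in 1 control array alone, sex was not balanced between the groups. By limma, 0 of 4 Y-linked genes passed adjusted over the list alone or over all genes (0 at an unadjusted p under 0.05), and camera gave adjusted p = 0.283.

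**Figure D3:**
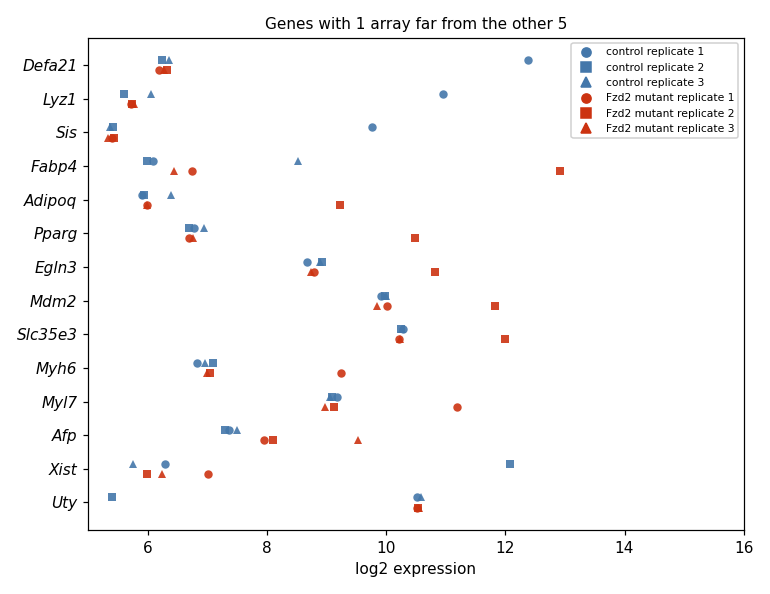
Log2 expression of 14 genes in each of the 6 arrays (blue, control; red, Fzd2 mutant; symbols, replicates 1 to 3), chosen after their values were seen. For each gene 1 array lies far from the other 5: control replicate 1 for Defa21, Lyz1 and Sis, mutant replicate 2 from Fabp4 to Slc35e3, mutant replicate 1 for Myh6 and Myl7, mutant replicate 3 for Afp, and control replicate 2 for Xist and Uty.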

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

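Leaving out control replicate 1 and mutant replicate 2 together, removing genes seen in 1 array alone, and counting list members without single arrays were chosen after the data had been seen; the other alternatives were planned. The count of 14 genes moved with most of them. By limma it was 8 after a further quantile normalization, 25 and 50 over genes above the 30th and 50th percentile of expression, where fewer genes are tested, 46 with a trended and robust variance, 27 without genes seen in 1 array alone, 57 at an adjusted p of 0.10, 778 (436 higher, 342 lower) at an unadjusted p of 0.01, and 8 when an absolute log2 difference of 0.58 was also required. It was 0 over every probe set (4981 at an unadjusted p under 0.05), 0 with the Y-linked mean as a covariate (1823), 0 with the pan-epithelial mean as a covariate (1323), 0 by an ordinary test without moderation (2426), 0 without control replicate 1 and mutant replicate 2 (2716), and from 0 to 0 when each array was left out (1797 to 3084); dropping arrays or adding terms leaves fewer degrees of freedom, and otherwise the cause was not tested. Median centring, averaged probe sets and array weights gave 17, 18 and 20. The 12 named genes of the 14 kept their direction wherever they were measured. With arrays left out the naming rule fixed this, and filters, variance models and the replicate block leave the differences themselves unchanged. All 12 stayed past the threshold with centring, the 30th percentile filter, averaged probe sets, the trended variance, array weights and the removal of genes seen in 1 array alone. With the replicate number as a block the limma count was 0 (2511 at an unadjusted p under 0.05) and the Fzd2 difference -0.29. The list count by camera was 11, without the canonical Wnt list (adjusted p = 0.0558). Deviations of arrays with the same number correlated at -0.04, -0.06 and 0.07. The highest correlations of the same control arrays with another mutant array were 0.04, 0.14 and 0.02. These values give no clear sign of pairing. They cannot exclude a shared litter or batch, since the signal of other tissues in single arrays enters them. The Fzd2 difference ranged from -0.41 to -0.10 with arrays left out, and turned to 0.38 (adjusted p = 0.873) with the pan-epithelial mean as a covariate. That covariate is nearly tied to the group and is itself a result. With it the lists called fell to 6, and the differences of Fzd10 (0.12), Fzd9 (-0.0827), Gata1 (-0.11), Fgb (-0.0513), Hapln1 (0.0641), Cdc6 (0.092), Rrm2 (0.11), Mcm2 (0.20) and Ccne1 (0.0391) and the medians of the canonical Wnt (0.0535), mitosis (0.11) and hypoxia (-0.29) lists changed sign. The list count was 0 by camera with an estimated correlation, 0 by fry, and from 10 to 15 under the remaining settings, single arrays left out included. With the Y-linked covariate Fzd6 was -0.13 and Fzd8 0.0118. That covariate acts much as leaving out control replicate 2 does, so the results of those fits are nearly the same. With arrays left out, Fzd9 ranged from 0.02 to 0.27, Fzd10 from -0.18 to -0.02, Fzd6 from -0.13 to 0.17, Fzd7 from -0.0722 to 0.0695, Fzd8 from -0.15 to 0.0169, Uty from -0.0209 to 2.57 and Eif2s3y from -0.0629 to 2.42, the last pair turning without control replicate 2, the only array without Y-linked signal. Pan-epithelial genes that passed over the list alone numbered 13 to 19 with arrays left out and 14 without both arrays high in genes of other tissues. Over all settings 1576 of 1776 refitted single-gene differences kept their direction and side of the threshold, 126 lost the threshold, 56 gained it and 18 changed sign. Of these, 213 were of the 12 genes past the threshold as reported, and 87 of the 213 stayed past it. Of 251 refits of the 12 called lists, 193 kept their direction and call, 55 lost the call and 3 changed sign. Camera was run from the expression values with its own default variance model, and the trended and robust setting was not passed to it. The 12 list results under that setting therefore repeat the reported ones and could not differ. RMA values keep no background level, so whether a dim gene lies above background was not analysed here.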

Other observations

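The gene lists of adult small intestine and adipose tissue, the values by array and the tests of explanations in this part were chosen after the results had been seen; fits without single arrays were planned.

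Genes known from tissues other than embryonic lung were high in single arrays. In control replicate 1, 25 of 27 measured adult small intestine genes had their highest value, 21 of them more than 1 log2 unit above every other array, with a median excess of 2.35. The Paneth cell defensin gene Defa21 stood at 12.37 against at most 6.36, the lysozyme gene Lyz1 at 10.96 against at most 6.05, the brush border enzyme gene Sis at 9.76 against at most 5.44, and the fatty acid carrier gene Fabp2 at 9.88 against at most 5.91. Cdx2, an intestinal transcription factor gene, was at 6.96 there and between 6.86 and 6.97 elsewhere. In mutant replicate 2, 17 of 17 adipose tissue genes were highest, 13 by more than 1 log2 unit, with a median excess of 2.39. The lipid carrier gene Fabp4 stood at 12.92 and the adipocyte regulator Pparg at 10.49, against at most 8.52 (control replicate 3) and 6.94. Over all genes, 66 in control replicate 1 and 58 in mutant replicate 2 lay more than 1 log2 unit above every other array, against 1, 0, 7 and 5 in control replicates 2 and 3 and mutant replicates 1 and 3. Between the groups the small intestine list mean differed by -0.86 (SE 0.94, exact permutation p = 0.8) and the adipose list mean by 0.79 (SE 0.79, exact permutation p = 0.5), less than the spread between arrays.

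Mutant replicate 2 also stood apart in genes of other kinds. The oxygen sensor gene Egln3 was at 10.81 against at most 8.91 and the mitophagy gene Bnip3 at 9.80 against at most 8.71. Mdm2 and its measured neighbour Slc35e3 were at least 1.73 log2 units above every other array, Mdm2 at 11.83 against at most 10.01. The other nearest measured genes, Cpm and Nup107 among them, did not follow, with differences of -0.26 and -0.20 from the highest other array.

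The median of the pan-epithelial genes was -0.18 without control replicate 1 and mutant replicate 2, the arrays high in genes of other tissues, against -0.26 with all arrays. Lower pan-epithelial genes were weighed against a smaller share of epithelial cells in the mutant lungs. That explanation needs nearly all epithelial genes to be lower, and 96.4% of those measured were, which a fall in their transcription in an unchanged number of cells would give too. This share is the result that raised the explanation, so it is not a separate test of it. It also needs markers of the other cell types to rise alike, where those cells keep their proportions to each other. They did not, since the mesenchyme mean rose against the smooth muscle mean by 0.26 log2 units (SE 0.03) and against the endothelial mean by 0.16 (SE 0.03). The mesenchyme and smooth muscle lists had already been called in opposite directions, so their contrast restates those calls. A smaller epithelial share may account for the epithelial genes. With the other cells in unchanged proportions it does not alone account for the other lists. Loss of Fzd2 in the epithelium, the difference the design names, stays open, untested, as a cause of both.

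The rise of p53 targets was weighed against the adipose and Mdm2 signal of mutant replicate 2. Without that array the list mean was still higher in mutants by 0.19 (SE 0.03), more than 2 standard errors above 0, and camera gave adjusted p = 0.00299, the highest of the values with any single array left out, which ran from 0.000170 (adjusted p = 0.258 with all arrays and an estimated correlation), so that array alone does not account for the rise. A smaller epithelial share alone was weighed too, which would raise the lists of other cell types alike. The p53 list rose above the endothelial list by 0.28 (SE 0.11) and above the smooth muscle list by 0.38 (SE 0.10). Without mutant replicate 2 these values were 0.19 (SE 0.07) and 0.31 (SE 0.08). Above the mesothelial list it rose by 0.14 (SE 0.11), within 2 standard errors. With so few arrays 2 standard errors is a lenient limit, which the endothelial contrasts passed by little. The smooth muscle list had itself been called lower, so its contrast partly restates that call. These contrasts therefore leave a smaller epithelial share open. A larger share of mesenchymal cells stays open as well, since the p53 list rose above the mesenchyme list by 0.13 (SE 0.08), within 2 standard errors. Of the 21 genes of the mesenchyme list 7 had lower means, so that list is an uneven measure of this share. A p53 response to Fzd2 deletion or to Cre activity at the floxed gene is a possible explanation that was not tested, since no array holds a floxed gene whose loss has no effect.

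Ccdc43, which has 2 measured genes between it and Fzd2, was higher by 0.59 (SE 0.07) in mutants with the 3 mutant arrays above all controls, just outside limma's threshold (adjusted p = 0.0509). A change of like size over the whole region was not seen: 0 of the other 19 nearest measured genes came within 2 standard errors of it and the highest of them reached 0.23. Ccdc43 was picked for its small p, so it was likely to stand out from its neighbours. A regional effect that differs between genes was not tested. Of the 20 neighbours, 3 were at an unadjusted p under 0.05 and 0 were called by limma (Fisher's exact p = 0.731 against all other genes). An effect of the altered Fzd2 allele on Ccdc43 itself cannot be told apart from an effect of losing Fzd2, since no array carried the altered allele with Fzd2 intact and its value is the same 0.59.

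The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 14 genes by limma and the highest of the others 0, so that 1 of the 10 splits gave as many, with 2770 genes at an unadjusted p under 0.05 against at most 1487. For gene lists the real split gave 12, each of the others gave at least 4 and the highest 16, in the split that set control replicate 1 and mutant replicates 2 and 3 against the rest, and 3 of the 10 splits gave at least as many.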
